A study of Escherichia coli BL21(DE3) with 5 samples.

How the data were processed

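Growth was in batch fermentations at 37 °C in LB or in modified R minimal medium (MR), and culture broth was mixed with an RNA stabilising reagent, per the labels' protocols. Total RNA was prepared with a kit that keeps small RNA, treated with DNase and labelled directly with Cy3, with no copying into cDNA named, per the labels' protocols. Each of the 5 samples was hybridised to its own array, and the labels put each in a group of its own by medium, OD600 and growth stage. The arrays came from 5 slides scanned on 3 days, per the file headers: the 3 LB arrays on the same day, and each MR array on a day of its own. Medium, and for a single gene the growth phase in MR, can therefore not be separated from the scan day, while the LB comparisons lie within 1 day.

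The scanner files were made by the authors with Agilent Feature Extraction 11.5.1.1 and its single-colour protocol, per the file headers. From them the processed signal was used, a linear intensity that Feature Extraction had background-subtracted and detrended within each array before the files were deposited, together with the median spot and local background intensities. Other columns used were the 0 or 1 marks that the authors' software gave for spots well above background, saturated spots and outlier spots, per the file headers. The authors' deposited value table held linear intensities for 956329 probes in 5 columns, and every column was matched to its array. Its columns had nearly the same sorted values, with medians of 25.4 to 25.6, as quantile normalization gives, and correlated on the log2 scale with the scanner signal at 0.994 to 1.00. The step that made this table and any filter before deposit are not given in the sources used here. The names of the chromosomal probes carry the identifier of a BL21 reference sequence.

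Each array had 973566 spots, of which 6001 were controls. Probe names gave 453652 fwd tiles and 451201 rev tiles of the chromosome, numbered up to 455896, and 50997 gene probes of 3537 gene tags, with a median of 16 probes per tag and 4 tags with fewer than 10. Tags with a t or an r before the number were taken as tRNA (29 tags, 416 probes) and rRNA (1 tag, 13 probes). Levels of neighbouring tiles are not independent: on the fwd strand of the LB OD1.54 array they correlated at 0.951, and at 0.810 when 5 tile numbers apart. The spacing of tiles in bases is not given in the sources used here, so stretches are given by tile number, with no coordinates. The gene table used here was of another strain's assembly and matched 0 tags, so no tag has a name. The gene lists, the fixed genes and the sense, antisense and intergenic classes that were planned could not be formed without names and positions, and are not reported.

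Levels were log2 of the processed signal minus the array's 75th percentile over the 412023 probes (42.6%) well above background on all 5 arrays, since under 0.5 of the probes passed on the MR OD14 array. Control spots and 192 to 235 outlier spots per array were left out. A gene's level was the median over its probes, and its difference is that of the levels of a pair of arrays. A tag was tested with at least 10 probes and a share of at least 0.5 of them well above background on at least 1 of the arrays compared. It was called higher or lower where the log2 difference was at least 1 in size and a share of at least 0.8 of its probes differed in that direction. With 1 array per group no test was run, and the number of arrays limits the precision: a call describes a pair of arrays and not the conditions. The groups, comparisons, calling rule, named-gene rule and most alternatives were fixed before the data were examined.

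The named-gene rule took, among tags passing the call with a share of at least 0.5 of their probes above background on both arrays, the tag with the largest difference of each run of neighbouring tags on the same strand that all passed the same way. Because the tags have no names, only the leading 2 of each direction are given. Neighbours were taken from the order of tag numbers, since the planned limit on the distance between genes needs coordinates. Runs of at least 3 changed tags were compared with 200 shuffles of the calls over all tested tags. Stretches of tiles were found with a running median over 31 tiles of the difference between arrays, at least 1 in size, over at least 100 tiles with a share of at least 0.5 above background. This rule for stretches was chosen after seeing the data. A fold given for a stretch comes from the difference of its median levels on the arrays compared. A log2 difference given for a stretch is the median of the differences of its tiles, and these measures can differ. A stretch whose tiles were mostly not above background on the dimmer array has a bound only, with the lowest level among probes well above background of that array in its place, and is given as at least so many-fold. The count expected of overlapping lists if independent is the product of their sizes over the number of tags tested in both.

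Alternatives tried were the 75th percentile over all probes, centring on the median of the tested tags, quantile normalization, normexp background correction (offset 50, limma 3.58.1 in R 4.3.3), the authors' value table, the mean of probes, other filters on detection, no minimum share of probes in a direction, saturated spots left out and LB OD0.24 as the LB reference. Normexp used the median spot signal, because the mean signal is not among the columns used here. Scaling to the tRNA and rRNA probes was added after the data were seen. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The calling step was tested on simulated data for LB OD5 against LB OD1.54 with 2983 tags. Of 50 tags each, it called 50 that were made 3-fold higher, 41 made 3-fold lower, 50 made 8-fold higher and 45 made 8-fold lower, and 0 of 2783 unchanged tags. The simulated array was the LB OD1.54 array at a lower gain, with independent spot noise and a background floor. It held no difference of culture, labelling or slide, so the 0 is not a rate of false calls between real arrays. The missed tags were dim, with a median signal of 32.9 for the 3-fold and 18.9 for the 8-fold falls, against 478 and 460 for those found.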

Results

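Escherichia coli BL21(DE3), a B strain carrying the DE3 prophage that is widely used to produce proteins, was grown at 37 °C in batch fermentations in complex LB medium or in MR, a modified R minimal medium. Total RNA was labelled directly with Cy3 and hybridised to 5 single-colour arrays whose probes tile both strands of the chromosome, 1 array per group. In LB the groups were a culture at an OD600 of 0.24 and another at 1.54, both exponential, and a stationary culture at 5. In MR they were an exponential culture at 1.5 and a stationary culture at 14. The series follows the growth curve in both media, so the growth phases were compared within each medium and the media within each phase. Genes are given by the array's own locus tags, because the tables used here paired none of the 3537 gene tags with a gene name. With 1 array per group no difference has a replicate check and no p-value is given. A value after ± is the SD of the difference over the probes of a gene, with n the number of probes, and between spots repeated on an array the SD of the log2 difference was 0.23 to 0.53.

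Most gene tags gave signal in every group. At least 0.5 of a tag's probes were well above background for 2850 tags at LB OD0.24, 2983 at LB OD1.54, 2690 at LB OD5, 2998 at MR OD1.5 and 2435 at MR OD14, and 2281 tags passed on all 5 arrays while 410 passed on none. Over all non-control probes the share well above background was 57.9% at LB OD0.24, 58.1% at LB OD1.54, 53.1% at LB OD5, 61.9% at MR OD1.5 and 47.4% at MR OD14. Gene probes passed more often (67.8 to 83.4%) than chromosomal tiles of the fwd strand (45.6 to 60.0%) or of the rev strand (47.5 to 62.4%), and negative controls passed at 0.208 to 0.415%. Both strands of a tile position were above background at 27.7, 25.9 and 21.7% of 451138 positions at LB OD0.24, OD1.54 and OD5, and at 32.4% and 16.1% at MR OD1.5 and OD14. Each of these shares was below the 32.6, 32.6, 27.3, 37.4 and 21.6% that independent strands would give. Annotation of sense and antisense strands was not used here, so these shares are by strand of the chromosome alone.

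Probes of stable RNA were far brighter than gene probes. The median unscaled signal of the 13 rRNA probes lay between 74528 and 153044, that of the 416 tRNA probes between 45242 and 68497, and that of the 50997 gene probes between 52.8 and 281. From LB OD1.54 to LB OD5 the unscaled signal of gene probes fell by 1.13 at the median on the log2 scale, a 2.18-fold difference, while tRNA probes changed by 0.10 and rRNA probes by 0.07. From MR OD1.5 to MR OD14 gene probes fell by 1.74, a 3.33-fold difference, while tRNA probes changed by 0.02 and rRNA probes by -0.10 at the median. Part of the stable RNA probes fell in MR too: over the 429 tRNA and rRNA probes together the quartiles of the change were -1.02 and 0.23 in MR, and -0.36 and 0.35 in LB. As a percentage of the tRNA and rRNA probe median, the gene probe median was 0.269 at LB OD0.24, 0.463 at LB OD1.54, 0.162 at LB OD5, 0.508 at MR OD1.5 and 0.0815 at MR OD14. All further differences are on the log2 scale after scaling each array to the 75th percentile of the probes above background on all 5 arrays, so they show a gene's change relative to other chromosomal probes and not its change per cell.

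**Figure D1:**
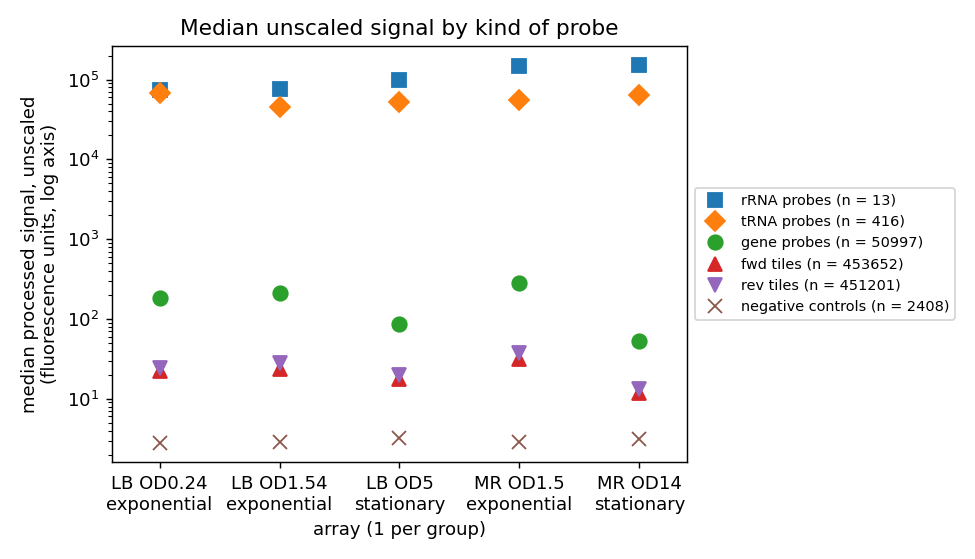
Median unscaled processed signal (fluorescence units, log axis) of each kind of probe on the 5 arrays, 1 point per array and kind. Gene probes drop to 87.2 at LB OD5 and 52.8 at MR OD14 while tRNA and rRNA probes stay above 45242.

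Within exponential growth in LB, 743 of 3040 tested gene tags were at least 2-fold higher at OD1.54 than at OD0.24 and 475 were at least 2-fold lower. The tag with the largest rise among those detected on both arrays was ECD_03991, at +8.41 ± 0.40 (n = 16 probes, 341-fold), and ECD_02078, in a run of 4 neighbouring higher tags, followed at +7.17 ± 0.36 (n = 13, 144-fold). The largest falls were smaller: ECD_01106 differed by -4.95 ± 0.33 (n = 12, 30.9-fold lower) and ECD_01917 by -4.48 ± 0.16 (n = 16, 22.3-fold lower). With normexp background correction these 4 differences were 7.40, 4.81, -3.45 and -4.28. The fold of ECD_02078 rests on a dim level of -6.53 at OD0.24, with 61.5% of its probes well above background. The lowest level of any such probe on that array was -6.61. The tiles gave 240 higher and 195 lower stretches, led by fwd tiles 377718 to 378089, where OD1.54 was at least 525-fold above OD0.24, at which most of these tiles were not well above background, and by fwd tiles 424894 to 425336, 139-fold higher. Among 28 tRNA tags 2 were lower and none was higher, with 5 lower when the percentile was taken over all probes and 0 after quantile normalization. Of the changed tags 61.0% were higher, against 49.4% when the percentile was taken over all probes 50.4% when the tested tags were centred on their median and 70.7% (891 higher, 369 lower) with scaling to the tRNA and rRNA probes. With normexp 455 tags were higher, and 162 of the 743 higher tags were not detected at OD0.24.

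Entry into stationary phase in LB, taken as OD5 against OD1.54, had 976 of 3034 tested tags at least 2-fold lower and 663 at least 2-fold higher. With OD0.24 as the reference the numbers were nearer each other, 1012 lower and 936 higher of 2997, of which 710 and 583 were shared, and 63 tags were called the opposite way. ECD_01008 was higher by 8.62 ± 0.28 (n = 16, 394-fold) and ECD_01233 by 7.66 ± 0.74 (n = 13, 202-fold). ECD_03593 was lower, at -8.14 ± 0.49 (n = 16, 283-fold), as was ECD_03591, at -6.71 ± 0.45 (n = 12, 104-fold), in a run of 6 lower neighbours. These last tags were bright on the OD1.54 array alone: no probe of either was well above background at OD0.24, so against that array OD5 has bounds only, higher by at least 1.99 and at least 3.23. With normexp the 4 differences from OD1.54 were 8.32, 5.71, -6.36 and -5.72, and with scaling to the tRNA and rRNA probes 7.44, 6.47, -9.33 and -7.89. Fwd tiles 377718 to 378247, which overlap the stretch that appeared at OD1.54, were 79.8-fold lower at OD5, and fwd tiles 31826 to 32432 were 93.5-fold higher. A stretch of 2286 fwd tiles, 76733 to 79018, was higher by 2.58 at the median, and it was the longest in any comparison. Of 28 tRNA tags 19 were higher relative to the scaled probes, 7 after quantile normalization and 0 when the arrays were scaled to the tRNA and rRNA probes. Higher tags made up 40.5% of those changed, against 56.0% with normexp, which left 522 lower tags, and 14.2% with scaling to the tRNA and rRNA probes, which gave 306 higher and 1846 lower. That last scaling moved the median over all tested tags from -0.35 to -1.53. Without the filter on detection 1004 tags were higher and 976 lower, where tags at background on both arrays count as higher by the scaling alone.

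**Figure D2:**
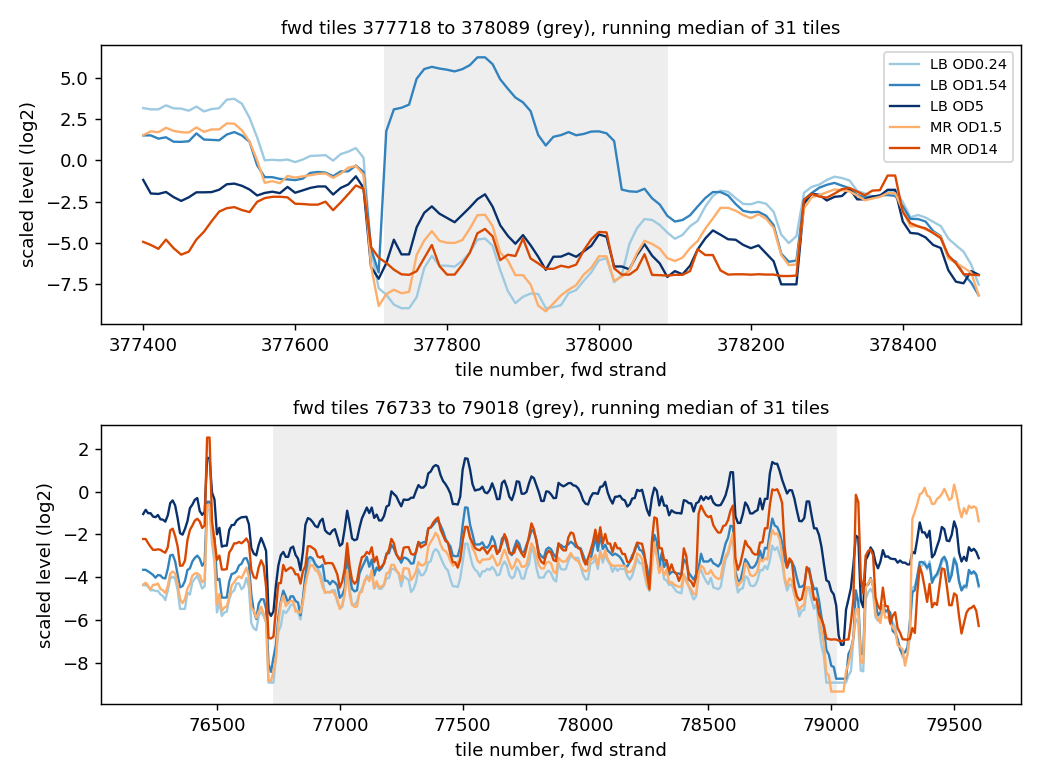
Scaled level (log2, running median of 31 tiles) along tile numbers of the fwd strand on the 5 arrays, 1 line per array, with the stretch named in each panel title in grey. The upper stretch is high on the LB OD1.54 array alone, and the lower one is highest at LB OD5, by 2.58 over LB OD1.54.

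In MR the stationary comparison held the most changed tags of the 5: of 3034 tested tags 1019 were at least 2-fold higher at OD14 than at OD1.5 and 964 at least 2-fold lower. Differences of at least 16-fold numbered 203 higher and 187 lower, compared with 87 and 43 between OD1.54 and OD5 in LB. With LB OD0.24 as the LB reference, 936 tags were at least 2-fold higher and 1012 lower of 2997. How far MR exceeded LB therefore depends on the LB reference, and 16-fold differences were not counted against OD0.24. ECD_01170 was higher by 9.67 ± 0.34 (n = 16, 816-fold) and ECD_02065 by 8.57 ± 0.43 (n = 12, 380-fold), and the levels of both were also higher at LB OD5 than at either exponential array in LB. ECD_04069, in a run of 4 lower tags, differed by -7.71 ± 0.25 (n = 13, 210-fold lower) and ECD_03652 by -7.58 ± 0.21 (n = 16, 192-fold lower). With normexp these 4 differences were smaller in size by 1.67, 0.61, 1.96 and 1.73, and with scaling to the tRNA and rRNA probes they were 7.07, 5.97, -10.31 and -10.19. ECD_04069 was dim at OD14, at -4.37 with 69.2% of its probes well above background. The lowest level of any such probe on that array was -4.83. Rev tiles 122316 to 122542 were 367-fold higher and fwd tiles 390573 to 390900 were 195-fold lower, with median tile differences of 8.44 and -6.67. The longest higher stretch, rev tiles 354858 to 355760, was 4.03-fold higher in MR and higher by 0.24 on the log2 scale in LB, and it differed by -0.60 in MR when the arrays were scaled to the tRNA and rRNA probes. The 28 tRNA tags were higher at the median by 2.39, by 0.46 after quantile normalization, and differed by -0.21 when scaled to the tRNA and rRNA probes themselves. Higher tags made up 51.4% of those changed, 72.3% with normexp (1420 higher, 544 lower, 32 tags called the opposite way) and 9.80% with scaling to the tRNA and rRNA probes (246 higher, 2263 lower), under which 261 tags called higher became lower and the median over all tested tags moved from 0.00 to -2.61. The MR arrays were scanned on different days, so for a single gene growth phase and scan day cannot be told apart in MR. Scan day alone does not account for the MR differences as a whole: those of LB OD5 against OD1.54, measured on other arrays within 1 scan day, correlated with them at 0.76 across 2966 tags (95% interval 0.73 to 0.79 over blocks of 20 tags in tag order drawn with replacement).

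**Figure D3:**
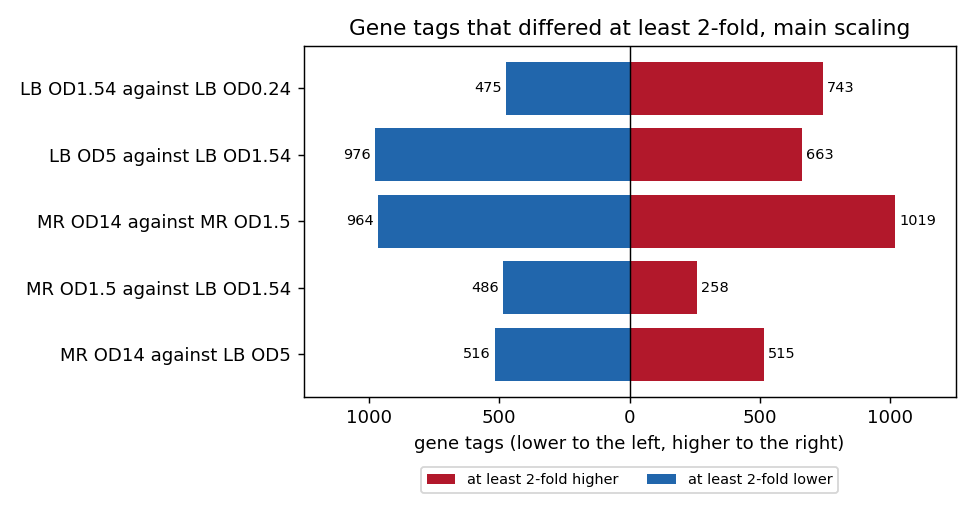
Number of gene tags at least 2-fold higher (right) and at least 2-fold lower (left) in each of the 5 comparisons, each between 2 arrays. The stationary comparison in MR has the most, 1019 higher and 964 lower, and the exponential comparison of the media the fewest, 258 and 486.

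At nearly equal density in exponential growth, 258 of 3058 tested tags were at least 2-fold higher in MR than in LB and 486 at least 2-fold lower. ECD_00536, in a run of 5 tags higher in MR, differed by 6.96 ± 0.25 (n = 16, 125-fold) and ECD_03309 by 6.03 ± 0.14 (n = 13, 65.5-fold). ECD_03991 was lower in MR, at -10.61 ± 1.06 (n = 16, 1559-fold), and so was ECD_03591, at -7.61 ± 0.33 (n = 12, 195-fold). With normexp these 4 differences were 6.44, 5.54, -8.46 and -6.90, and with scaling to the tRNA and rRNA probes 7.44, 6.51, -10.13 and -7.14. ECD_03991 was low at LB OD0.24 too, with a scaled level of -4.54 there, 3.88 at LB OD1.54 and -6.73 at MR OD1.5. At MR OD1.5 62.5% of its probes were well above background, where the lowest level of any such probe was -7.02. Its fold against LB OD1.54 therefore rests on a level near background. Fwd tiles 55422 to 56253 were 58.9-fold higher in MR, and fwd tiles 424890 to 425343 were 254-fold lower. None of 28 tRNA tags differed 2-fold under any of the scalings run for them. Medium and scan day cannot be told apart, since the MR arrays and the LB arrays were scanned on separate days. Higher tags made up 34.7% of those changed and 65.7% (474 higher, 247 lower) with scaling to the tRNA and rRNA probes, which moved the median over all tested tags from -0.24 to 0.24.

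Between the stationary cultures, MR OD14 against LB OD5, 515 of 2733 tested tags were at least 2-fold higher in MR and 516 at least 2-fold lower, with 8 and 14 past 16-fold. ECD_02848, in a run of 5 higher tags, differed by 5.45 ± 0.26 (n = 16, 43.8-fold) and ECD_02990 by 5.15 ± 0.33 (n = 13, 35.4-fold). ECD_03991 was again lower in MR, at -8.17 ± 0.45 (n = 16, 287-fold), followed by ECD_01701 at -4.27 ± 0.77 (n = 16, 19.2-fold). With normexp these 4 differences were 4.09, 4.20, -6.63 and -2.51, and with scaling to the tRNA and rRNA probes 4.51, 4.20, -9.11 and -5.21. ECD_01701 was dim at MR OD14, at -4.17 with 56.3% of its probes well above background. The lowest level of any such probe on that array was -4.83. Rev tiles 313676 to 314116 were 25.5-fold higher in MR, and a stretch of 1601 fwd tiles, 76857 to 78457, was lower by -2.44 at the median. Cell density and scan day differed as well as the medium. Higher and lower tags were nearly equal in number, whereas 68.6% of the changed tags were higher with normexp (159 lower) and 10.2% with scaling to the tRNA and rRNA probes (144 higher, 1271 lower), which moved the median from 0.04 to -0.91, and 339 tags were lower among those detected on both arrays.

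The stationary differences of the media, which share no array, went the same way for most genes changed in both. Across 2966 tags Pearson's r was 0.76 and Spearman's rho 0.77, where tags are not independent replicates. Of these tags 544 were at least 2-fold higher in both media and 676 at least 2-fold lower in both, against 216 and 310 for independent lists of the same sizes. Only 59 tags went opposite ways, against 531 for independent lists: 48 were lower in LB and higher in MR, and 11 were higher in LB and lower in MR. A further 323 tags changed in LB alone and 678 in MR alone by the 2-fold rule, a count in which no difference between the media was tested. Scaling to the tRNA and rRNA probes gave 171 tags higher in both and 1698 lower in both.

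**Figure D4:**
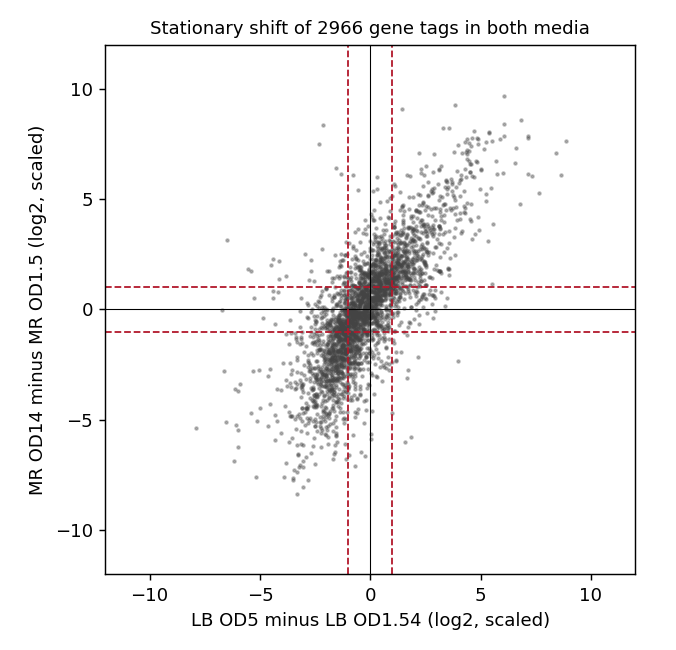
Stationary minus exponential difference (log2, scaled) of 2966 gene tags in LB (x axis) and MR (y axis), 1 point per tag, with dashed lines at 2-fold. Points lie along the diagonal (r = 0.76), and 59 tags lie beyond 2-fold in opposite directions.

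The media differences of the exponential cultures showed little relation to those of the stationary ones. Across 2689 tags r between them was 0.01 and rho -0.11, and 32 tags were higher in MR in both phases and 68 lower in both, against 35.4 and 76.3 for independent lists. Under the main scaling the commonest combination was lower in MR in exponential growth and higher in MR in stationary phase, with 116 tags against 75.6. These overlaps were not counted under another scaling, so this ranking holds for the main scaling alone. Scaling to the tRNA and rRNA probes gave lists of other sizes: 474 higher and 247 lower in exponential growth, and 144 and 1271 in stationary phase.

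Along the LB growth curve, 234 tags were higher at OD1.54 than at OD0.24 and higher again at OD5, and 228 were lower at both steps, against 154 and 147 for independent lists. A rise and then a fall was seen for 222 tags (243 for independent lists) and a fall and then a rise for 41 (93.3). These counts hold for the main scaling and were not made under another. Scaling to the tRNA and rRNA probes gave 891 higher and 369 lower tags at the first step, and 306 and 1846 at the second. The longest stretch of the first step's falls, rev tiles 330070 to 331459, differed by -1.90 at the median, then by -2.21 from OD1.54 to OD5, and by -4.72 from MR OD1.5 to MR OD14. Both steps share the OD1.54 array, and arrays simulated as unchanged around it gave 0 tags called at both steps, a covariance of -0.01 and a correlation of -0.51, where the measured covariance was 0.24 and the correlation 0.08 across 2988 tags. The simulation holds spot noise alone, so anything particular to the single OD1.54 culture or array would still appear as a rise followed by a fall or as a fall followed by a rise.

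Changed genes lay together on the chromosome. In runs of at least 3 tags next to each other in tag order, on the same strand and changed the same way, there were 402 tags at LB OD1.54 against OD0.24, 502 at LB OD5 against OD1.54, 584 at MR OD14 against OD1.5, 174 at MR OD1.5 against LB OD1.54 and 180 at MR OD14 against LB OD5. When the calls were shuffled 200 times the means were 49.5, 116, 184, 12.9 and 31.5, and the highest values 84, 167, 250, 35 and 59. The longest run held 24 tags higher at LB OD5. Differences of neighbours on the same strand correlated across pairs at 0.51 to 0.70, and those of neighbours on opposite strands at 0.07 to 0.19, which uses the order of tag numbers and not distances.

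The array also carried tiles of a construct named H6MBPlacEGF. Its 72 fwd tiles had a median unscaled signal of 91.1 at LB OD0.24, 1100 at LB OD1.54, 208 at LB OD5, 876 at MR OD1.5 and 16.8 at MR OD14. Of 60 fwd tiles well above background on the LB OD1.54 array, where the construct was brightest, 56 were tiles 1 to 56, none lay in tiles 57 to 67, and 4 were tiles 68 to 71, with signals of 26.0 to 52.3. Tiles 68 to 71 were also above background at MR OD14, at 22.1 to 82.7, and tile 63 was above it at LB OD5 alone. A stretch of chromosomal rev tiles, 415258 to 415368, followed tiles 1 to 56 with a correlation of 0.90 over tiles and arrays. The match was in reversed order, at a spacing of 2 chromosomal tiles per construct tile.

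**Figure D5:**
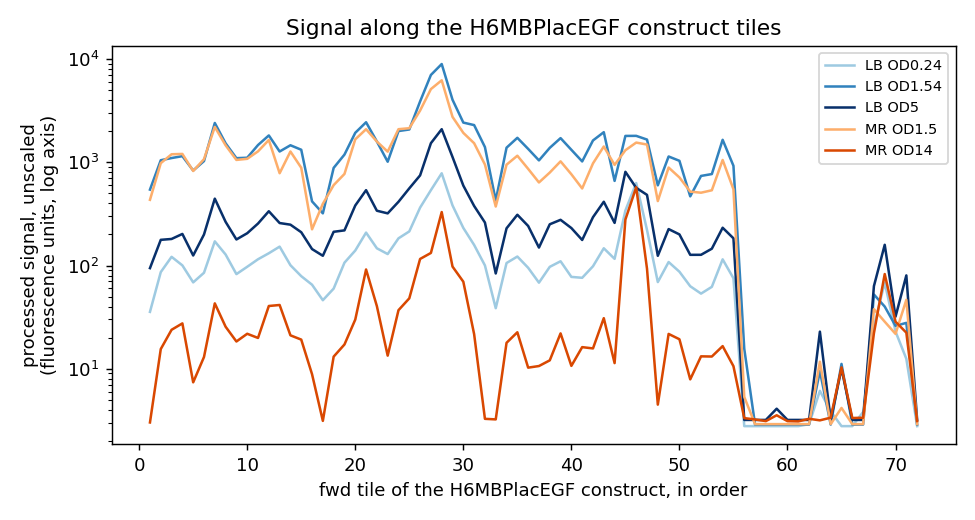
Unscaled processed signal (fluorescence units, log axis) along the 72 fwd tiles of the H6MBPlacEGF construct, 1 line per array. Tiles 1 to 56 are brightest at LB OD1.54 (median 1338) and dimmest at MR OD14 (median 19.2), tiles 57 to 67 have medians of 2.77 to 3.27, and tiles 68 to 71 show signal again.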

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

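The search at wider tile spacings was chosen after the result it bears on was seen. The other tests of this part were written before.

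Tiles of a construct that no label mentions gave signal. On the array with the lowest share, MR OD14, 52.8% of the 72 fwd tiles and 15.3% of the 72 rev tiles of H6MBPlacEGF were well above background, and at LB OD1.54 the fwd share was 83.3%, against at most 0.415% of 2408 negative controls. RNA of the whole construct needs signal along all of it, but 11 consecutive fwd tiles, 57 to 67, were not well above background on the LB OD1.54 array, where it was brightest, between tiles 1 to 56 and tiles 68 to 71, which were, and this argues against it. A chromosomal stretch that shares sequence with tiles 1 to 56 at the same tile spacing is argued against by a best correlation of 0.81, under the 0.9 set beforehand. At wider spacings rev tiles 415258 to 415368 reached 0.904, with the best elsewhere at 0.80. That match was at a spacing of 2 chromosomal tiles per construct tile, with the tiles in reversed order. Shared sequence at a wider spacing may be a source of the signal on tiles 1 to 56 and stays open, as does RNA of a part of the construct: the median levels of the 2 stretches lay within 0.06 (log2) on all 5 arrays, but 0.904 is under the 0.95 set for that search, and neither the tile spacing nor the probe sequences are given in the sources used here. Tiles 68 to 71 were not part of these searches, and the groups name no construct, so no biological explanation was tested.

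Tiles of another construct, pTSN_lycopene_MVA2, were well above background at no less than 16.8% of 543 fwd tiles and 6.01% of 549 rev tiles, both lowest at MR OD14. Of 10000 probes whose names begin with ncp, at least 16.4% were well above background, lowest at MR OD14 and highest at LB OD5 with 21.0%.

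Some genes changed in opposite directions on entry into stationary phase in the 2 media. By the 2-fold rule 48 tags were lower in LB and higher in MR, and 11 were higher in LB and lower in MR, each medium with 1 array per phase, and the difference between the media was not tested. Scaling to the tRNA and rRNA probes gave 16 and 40.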

How the results depend on the processing

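Scaling to the tRNA and rRNA probes, and the alternatives for tile stretches, for tRNA tags and for the tags changed in both media, were chosen after seeing the data. Leaving out saturated spots changed no count, named difference or stretch and is left out of the numbers that follow. Of 102 alternative values of the 10 counts of tags at least 2-fold higher or lower, 88 stayed within 1.5 times the reported count, and 6 of the 92 planned ones moved further. With normexp these were 455 higher at LB OD1.54 against OD0.24, 522 lower at LB OD5 against OD1.54, 544 lower at MR OD14 against OD1.5 and 159 lower at MR OD14 against LB OD5. No filter on detection gave 1004 higher at LB OD5 against OD1.54 over 3533 tags, with 976 lower as before. Negative controls had median scaled levels of -8.76 at LB OD1.54 and -7.50 at LB OD5. A tag at that background on both arrays therefore counts as higher by the scaling alone. Detection on both arrays gave 339 lower at MR OD14 against LB OD5, by testing fewer tags. Scaling to the tRNA and rRNA probes gave 306 higher and 1846 lower at LB OD5 against OD1.54, 246 and 2263 at MR OD14 against OD1.5, 474 and 247 at MR OD1.5 against LB OD1.54, and 144 and 1271 at MR OD14 against LB OD5, since it moves every tag of an array by the same amount. For normexp the cause was not tested. The correlation of the stationary shifts was 0.81 with LB OD0.24 as reference, 0.78 with normexp, 0.76 with the authors' values and 0.78 over tags detected on all 4 arrays. With the 99th percentile of the negative controls as the limit, detection at LB OD0.24, OD1.54, OD5, MR OD1.5 and MR OD14 was 86.9, 88.0, 85.4, 88.3 and 79.6% of gene probes, 72.9, 68.2, 69.8, 71.5 and 62.2% of fwd tiles, and 74.2, 70.0, 71.2, 73.5 and 63.7% of rev tiles, lowest at MR OD14 as before. Under that limit the share of tiles rose from LB OD1.54 to LB OD5. By the software's marks it fell, from 56.1 to 51.5% of fwd tiles and from 58.2 to 53.0% of rev tiles. The filters on detection and on the share of probes choose tags and cannot change a named difference. Of 144 values under the other alternatives of the 20 named differences, 82 moved by less than the probe SD, 60 moved further and 2 reversed. Normexp made all 20 smaller, by 1.15 to 5.14-fold. The reversed ones were ECD_03593 and ECD_03591 at LB OD5, measured at 3.58 and 3.83 against LB OD0.24, where neither was above background, so that only at least 1.99 and at least 3.23 hold. Of 200 values of 40 tile stretches 1 reversed, rev tiles 354858 to 355760 at MR OD14 against OD1.5, at -0.60 when scaled to the tRNA and rRNA probes, and 25 moved by more than the SD over tiles. Gene list medians with their rotations along the chromosome, the sense, antisense and intergenic classes and the alternative with probes that do not overlap were planned and not run, for lack of gene names, positions and probe sequences. No paired analysis was possible because each group has 1 array. Signal over background limits both rises and falls, since a level not above it is only a bound, but not equally. At LB OD1.54 against OD0.24, 162 higher tags were dim on the reference and 26 lower ones on the other array. At MR OD14 against OD1.5 the numbers were 36 and 316, so there falls were limited more often than rises.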

Other observations

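Tests chosen only after the result was seen are that of overall gain, that of the gene probe level relative to stable RNA and that of a gradient in LB alone. The intervals over tags were added after the result was seen too. The test of a gradient in both media was written before, and so was that on equally bright probes, with a limit at the brightest 10% of gene probes, but matching up to the brightest gene probe and within 0.25 of each level was not part of what was written, and the values below that 10% were added after the result was seen.

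The tags that went opposite ways in the stationary phases of LB and MR lay partly together. Of the 59, 23 lay in 9 runs of at least 2 neighbours on the same strand. The longest was 5 tags on the rev strand, with a median of -2.70 in LB and 2.02 in MR, and another 4 tags on the rev strand had -1.85 in LB and 6.96 in MR. The brightest long stretches of tiles on the MR OD14 array, at a median scaled level of 9.89 to 10.07, were fwd tiles 22647 to 22839, 22856 to 23147, 383193 to 383374, 383391 to 383725, 394221 to 394412, 394601 to 394721 and 407683 to 407996, and rev tiles 328455 to 328768. Of the 543 pTSN_lycopene_MVA2 fwd tiles 87 were well above background on all 5 arrays, and part of the signal lay in short stretches. The 9 fwd tiles 528 to 536 had a median signal of 73539 at LB OD0.24, 16127 at LB OD1.54, 3370 at LB OD5, 27354 at MR OD1.5 and 2471 at MR OD14, and the 25 tiles 316 to 340 had 250, 133, 277, 136 and 596. Of the 10000 ncp probes 74.1% were well above background on no array and 13.8%, or 1382, on all 5, and the levels of these 1382 correlated between arrays at 0.91 to 0.96.

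Gene probes were dimmer on both stationary arrays than on the exponential arrays of the same medium. Lower overall gain of those arrays would lower the tRNA and rRNA probes as much, but their median change lay above that of gene probes by 1.22 in LB (95% interval 1.13 to 1.28 over tags drawn with replacement) and 1.74 in MR (1.68 to 1.85). These intervals hold no variation between arrays. The values argue against gain as the whole cause in LB. In MR they do so only if brightness did not hide a fall of the tRNA and rRNA probes, whose lower quartile there was -1.02. The brightness of these probes hiding a fall is argued against in LB, while in MR the limit written beforehand does not decide it. Below the brightest 10% of gene probes, 118 tRNA and rRNA probes in each medium were compared with gene probes of equal brightness. In LB they changed by a median of -0.15 and lay 1.12 above those gene probes (interval 0.60 to 1.73, lower quartile 0.06). In MR they changed by -0.90 and lay 1.05 above (lower quartile -0.11). The MR interval of 0.38 to 1.85 reaches under the 0.5 set beforehand. Matched up to the brightest gene probe, tRNA and rRNA probes lay 1.90 above in LB (234 probes, lower quartile 0.31). In MR the probes matched that way changed by a median of -0.66 and lay 1.87 above (237 probes, lower quartile 0.37). A lower share of mRNA in the total RNA of stationary cultures may be the source: relative to the tRNA and rRNA probes the higher of the stationary arrays differed by -0.73 from the lowest exponential array. The exponential arrays themselves ran from -8.54 at LB OD0.24 to -7.62 at MR OD1.5, a wider range than that gap. LB OD5 lay at -9.27 and MR OD14 at -10.26. A lower share of mRNA stays open, because each group is 1 array labelled on its own, so a shift in mRNA content and one in labelling or recovery of short and long RNA cannot be told apart.

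In LB the stationary differences held a weak wave along the tag order, under larger differences from tag to tag. Over the 3034 tested tags the quartiles of the difference were -1.32 and 0.83. Neighbours on opposite strands correlated at 0.07. A single wave fitted to the difference of LB OD5 and LB OD1.54 had an amplitude of 0.396, against 0.20 at the 95th percentile of 1000 shuffles of blocks of 20 tags, with its peak at 29.4% of the tag order. In MR the amplitude was 0.17 and 390 of 1000 shuffles reached it, although the peak lay at 28.8%. Gene dosage along the replicating chromosome as a cause in both media alike did not pass the test set beforehand. The 95th percentile of the shuffles was 0.29 in MR, so an amplitude as large as that in LB would have exceeded it. A smaller wave in MR could not be told from the shuffles, so dosage in both media stays open. For LB alone gene dosage may contribute and stays open, because the place of the replication origin in the tag order and the growth rates are not given in the sources used here. The media difference of the exponential arrays had an amplitude of 0.19, reached by 4 of 1000 shuffles, with its peak at 27.8%. It shares the LB OD1.54 array with the LB stationary difference. LB OD1.54 against OD0.24 had an amplitude of 0.02, reached by 957.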
